A study of Homo sapiens with 16 samples.

How the data were processed

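Gene expression was measured by RNA sequencing in 16 libraries of human CD4+ T cells stimulated through CD3 and CD28. The cells came from blood mononuclear cells of patients with rheumatoid arthritis in groups called ATPlow and ATPint by the labels. Per the labels, ATPlow cells received vehicle or cyclosporin A (CsA, 5 uM, called an inhibitor of the mitochondrial permeability transition pore), and ATPint cells received vehicle or N-formylmethionine (fMet, 5 ng/ml). A time of 24 h is stated with the fMet treatment; for the ATPlow libraries no time is stated. Each of the 4 groups held 4 libraries. Messenger RNA was purified on poly-T beads and copied with random hexamers. The labels name a directional and a non-directional protocol without saying which was used.

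The authors deposited 1 table of counts per gene, 1 column per library, with whole numbers and no normalization. Their processing notes name HISAT2 2.0.5 for alignment to hg38, featureCounts 1.5.0-p3 for counting and DESeq2 1.20.0; the annotation release and the strand setting are not stated. The deposited table also gives a gene length in base pairs per the file headers, a value of another kind than the counts and not a measurement of a sample. The table held 58735 genes, of which 19951 were protein-coding. Genes on chromosome Y, XIST and TSIX (520 genes) were left out of all tests. Total counts per library ranged from 18225432 to 34465357. Reads without molecular identifiers are not independent molecules, so counting error is only part of the error; the spread over the 4 libraries of a group was used for all tests.

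Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM normalization, filterByExpr with a minimum count of 10 and a minimum total of 15). All 16 libraries entered 1 fit with 4 group means and no block, because the labels number the libraries of a group without stating that a number marks the same patient with vehicle and with drug. This fit takes all libraries as independent, although CsA and fMet libraries of the same number deviated together (Results). The spread used for every contrast may thus rest on fewer independent libraries than 16. The contrasts were CsA minus vehicle in ATPlow, fMet minus vehicle in ATPint, ATPlow vehicle minus ATPint vehicle, and the CsA response minus the fMet response. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the 15980 genes tested. The standard error of a log2 fold change was its size divided by the square root of F. Levels are given as CPM, counts scaled by edgeR to the normalized library size, with the SD over the 4 libraries of a group.

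Gene lists fixed before the data were examined covered lysosomal hydrolases and membrane proteins, vacuolar ATPase subunits, endosomal sorting and traffic, autophagy, mitochondrially encoded proteins, the nuclear-encoded respiratory chain, mitochondrial translation and formylmethionine handling, and mitochondrial pore, import stress and proteostasis. They also covered glycolysis, calcineurin-NFAT dependent activation genes, the Th1, Th2, Th17, regulatory and follicular helper programs, naive and central memory T cells, tissue homing, adhesion and invasion, and cytokines and chemokines of inflammation. The remaining lists were the type I interferon response, NF-kB targets, the integrated stress response, the unfolded protein response of the endoplasmic reticulum, cytosolic heat shock proteins, cholesterol synthesis and uptake, cell cycle and proliferation, the oxidative stress response, double strand break and mitochondrial DNA repair, apoptosis and pyroptosis, and cytosolic ribosomal proteins. Marker lists were fixed for CD4 T cells, monocytes and macrophages, B cells, NK cells, CD8 and cytotoxic T cells, platelets, red cells, dendritic cells and neutrophils. The 35 lists with at least 5 members tested were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjusted p values cover the 35 lists of a comparison. For each list, members were also adjusted over the list alone.

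The rule for named genes was fixed before the data were examined. It took protein-coding genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, up to 8 with the largest increase and up to 8 with the largest decrease. It added up to 3 called members of each list with at least 3 called members, and 16 genes named whatever their result. Where fewer than 10 genes passed, up to 8 genes per direction with the smallest p were named as not passing. HLA genes, immunoglobulin and T cell receptor segments, and genes that follow common deletions or known expression variants were tested and counted but not named.

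Other settings, chosen before the data were examined, were DESeq2 size factors and upper quartile normalization in edgeR, no filter on low counts, a filter of at least 1 CPM in at least 8 libraries, protein-coding genes only, the DESeq2 1.42.0 Wald test, an absolute log2 fold change of at least 1, only the 8 libraries of a comparison, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were a fit without the 4 libraries whose monocyte and macrophage markers summed to more than 100 CPM (a bound chosen after those sums were seen), that sum as a covariate, a correction for GC content and gene length (lowess trends with a span of 0.3 as offsets, sequence matched for 99.96% of the genes), a direct comparison of CsA and fMet libraries with the number as a block, and, for the difference of responses, a replicate block of the CsA and fMet libraries only (1 term per number, none for vehicle libraries). Library measures were compared with exact two-sided permutation tests over 70 assignments of 4 against 4, whose smallest p is 0.0286. Fold changes of different contrasts were correlated across genes, beside 20 simulated data sets without differences and 6 splits of the shared vehicle libraries.

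The fit was tested on simulated counts with the fitted spread and 200 changed genes. For CsA against vehicle it recovered 17.1% of genes changed 1.5-fold, 60% of those changed 2-fold and 90% of those changed 4-fold. For fMet against vehicle these shares were 14.3%, 45.7% and 76.7%, and for ATPlow against ATPint 7.14%, 50% and 85%. Of the unchanged genes, 8, 7 and 5 were called by edgeR and 41, 29 and 32 by DESeq2 in the same order. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.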

Results

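The data were 16 RNA sequencing libraries of stimulated CD4+ T cells from patients with rheumatoid arthritis, 4 each of ATPlow cells with vehicle, ATPlow cells with CsA, ATPint cells with vehicle and ATPint cells with fMet. CsA is an immunosuppressant that blocks calcineurin and also binds cyclophilin D of the mitochondrial permeability transition pore. fMet is the amino acid with which mitochondria start their proteins. Total counts per library were 19393260 to 34465357 in ATPlow with vehicle, 22027727 to 33350898 with CsA, 21330515 to 25967832 in ATPint with vehicle and 18225432 to 23750093 with fMet. The first principal component of log2 CPM held 37.2% of the variance. None of 43 measures per library (depth, shares of the most counted genes, mean of each list) passed an exact two-sided permutation test after adjustment in any of the 3 comparisons of 4 against 4, where 25 measures at the smallest possible p of 0.0286 would be needed to pass. At this p were 10 measures between ATPlow and ATPint, 3 for CsA and 5 for fMet (lowest adjusted p = 0.123, 0.410 and 0.246).

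CD4 was present in all libraries at 289 to 714 CPM and the T cell receptor component CD3E at 349 to 578 CPM. Markers of monocytes and macrophages summed to 697 CPM in ATPlow vehicle 3, 221 in ATPlow vehicle 4, 1598 in CsA 3 and 2176 in fMet 3, and to 21.1 to 62.1 CPM in the other 12 libraries. LYZ, the lysozyme of monocytes and other myeloid cells, made up most of each sum, with 488, 156, 1216 and 1729 CPM in these 4 libraries. In ATPlow vehicle 4 the markers CD14 (0.482 CPM), S100A9 (0.482) and CST3 (4.34) were lower than in fMet 1 (0.878, 0.790 and 8.51), which lay below the bound. TYROBP was higher there, at 19.8 against 8.20 CPM. The place of ATPlow vehicle 4 among the monocyte-rich libraries thus rests mostly on LYZ. Its B cell and NK cell marker means were 3.36 and 2.88 log2 CPM.

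**Figure D1:**
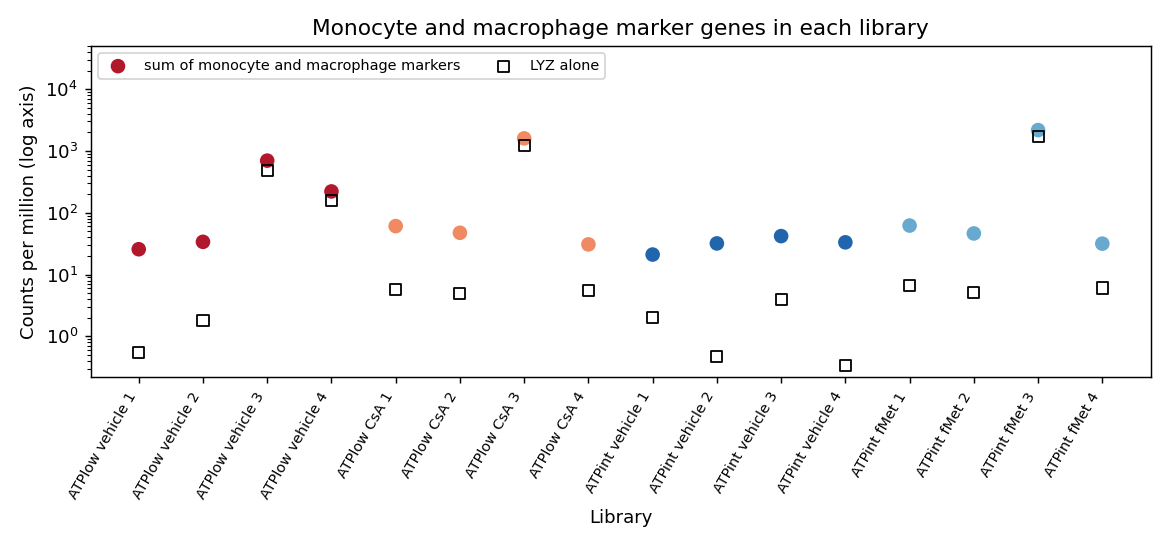
Monocyte and macrophage marker genes in the 16 libraries. The log axis gives CPM, filled points the marker sum coloured by group and open squares LYZ alone; 4 libraries lie above 100 CPM and the other 12 at 21.1 to 62.1 CPM.

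The comparison of ATPlow with ATPint cells under vehicle asks how stimulated cells of these patient groups differed without a drug. No time is stated for the ATPlow libraries, so the times in culture may differ. Higher in ATPlow was SQSTM1 (ENSG00000161011, hg38 chromosome 5, 179806398 to 179838078), which encodes a receptor for cargo of autophagy. It stood at 727 ± 53.7 CPM in ATPlow and 311 ± 69.2 in ATPint (SD, n = 4 each), a log2 fold change of 1.22 ± 0.13 (SE) with an edgeR adjusted p of 0.00100. IRS2, an adaptor of the insulin receptor, rose 3.27-fold and DDIT3, a transcription factor of the stress response, 3.70-fold. PIK3IP1, an inhibitor of phosphoinositide 3-kinase, rose 3.68-fold, P2RX7, a channel opened by extracellular ATP, 3.44-fold, and the circadian repressor NR1D2 3.61-fold. LY9, a lymphocyte surface receptor, rose 4.49-fold, TTC22 3.35-fold and the galactosyltransferase B3GALT2 11.5-fold from 0.192 CPM. Adjusted p of these 8 genes other than SQSTM1 lay between 0.00443 (IRS2) and 0.0280 (LY9), with no overlap between the groups.

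Genes lower in ATPlow included HILPDA, a lipid droplet protein induced by low oxygen, at 6.63 ± 1.99 CPM against 42.1 ± 15.4 (SD, n = 4; edgeR adjusted p = 0.0161). The sterol-binding protein gene OSBPL10 was 4.83-fold lower, HPDL 4.32-fold, the kisspeptin receptor gene KISS1R 3.68-fold, the actin binder LIMA1 2.93-fold and SH3D21 2.61-fold. The nucleoside transporter SLC29A1 was 2.57-fold lower and PNPT1, a nuclease of mitochondria, 2.55-fold. In all, 182 genes were higher and 218 lower in ATPlow of 15980 tested, or 232 higher and 190 lower with upper quartile normalization, and 3724 genes had an unadjusted p below 0.05 where 799 are expected by chance. With only the 8 libraries of this comparison edgeR called 0 genes (2754 unadjusted; DESeq2 called 1857 with all 16 libraries). Of the 400 called genes, 374 showed no overlap between the groups; among all genes 10.8% showed none, against 2.86% by chance.

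Glycolysis moved down as a group. Of its 24 tested members, 7 were lower and 17 did not pass, 16 were lower when adjusted over the list alone, and the median log2 fold change was -0.58 (camera adjusted p = 2.13e-11; adjusted p = 0.324 with an estimated correlation). LDHA, lactate dehydrogenase, stood at 625 ± 157 CPM against 1387 ± 338 (SD, n = 4; edgeR adjusted p = 0.0212). The glycolytic enzyme genes TPI1 and HK2 were each 2.10-fold lower. Of 45 genes of the cell cycle, 3 were lower, 42 did not pass and 16 were lower adjusted over the list alone (median -0.56, camera adjusted p = 1.04e-13; adjusted p = 0.385 with an estimated correlation). UHRF1, which keeps DNA methylation through replication, was 1.61-fold lower, and MCM4 and MCM5 of the replicative helicase were 1.67-fold and 1.52-fold lower. The nuclear-encoded respiratory chain had 2 lower and 74 not passing of 76 members, with 26 lower adjusted over the list alone (median -0.28, camera adjusted p = 5.28e-10; adjusted p = 0.468 with an estimated correlation). Cytosolic heat shock proteins had a median of -0.65 with 1 of 18 lower and 11 lower adjusted over the list alone (camera adjusted p = 1.35e-05, or 0.328 with an estimated correlation).

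The lysosomal list moved the other way. Of 51 members, 5 were higher and 46 did not pass, with 9 higher adjusted over the list alone (median 0.48, camera adjusted p = 7.48e-08; adjusted p = 0.468 with an estimated correlation). SLC17A5, the lysosomal exporter of sialic acid, rose 1.89-fold, SMPD1, acid sphingomyelinase, 2.08-fold and CTSF, cathepsin F, 2.16-fold. Vacuolar ATPase subunits, which acidify lysosomes, had a median of 0.27 with 1 of 17 higher and 2 adjusted over the list alone (camera adjusted p = 0.00119, or 0.542 with an estimated correlation). Autophagy had 2 of 39 higher, and 12 higher and 1 lower adjusted over the list alone (median 0.14, camera adjusted p = 0.000406; adjusted p = 0.324 with an estimated correlation). The integrated stress response had 2 of 31 higher and 9 adjusted over the list alone (median 0.59, camera adjusted p = 2.67e-06; adjusted p = 0.468 with an estimated correlation). Mitochondrial pore, import stress and proteostasis had a median of -0.28 (camera adjusted p = 3.74e-05; adjusted p = 0.385 with an estimated correlation), with 1 of 31 higher and 2 lower, and 2 higher and 9 lower adjusted over the list alone. The higher gene was PINK1, the kinase that marks damaged mitochondria, at 1.99-fold; DNM1L, which divides mitochondria, was 1.45-fold lower and VDAC1, an outer membrane channel, 1.74-fold lower.

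Monocyte-rich libraries were 2 of the 4 ATPlow vehicle libraries and 0 of the 4 ATPint vehicle libraries. Median log2 fold changes were 1.10 for 11 monocyte and macrophage markers, 2.78 for 10 NK cell markers and 1.68 for 10 B cell markers, with 0 members of these lists past the edgeR threshold over all genes or adjusted over the list alone; camera called the B cell list (adjusted p = 0.0179, or 0.806 with an estimated correlation). Unadjusted, 3724 genes had a p below 0.05, and DESeq2 called 1857 genes.

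Without the 4 monocyte-rich libraries 15 genes were called, 12 of them among the 400. The median of the cell cycle list went from -0.56 to -0.16, of the respiratory chain from -0.28 to -0.14, of the lysosomal list from 0.48 to 0.30, of glycolysis from -0.58 to -0.41, of autophagy from 0.14 to 0.23 and of mitochondrial pore, import stress and proteostasis from -0.28 to -0.18. Camera still called these lists (adjusted p = 9.36e-05, 0.000465, 1.26e-09, 2.80e-10, 0.000165 and 0.00192). The median went from 1.68 to 0.32 for B cell markers, no longer called by camera (0.357), and reversed for monocyte and macrophage markers (1.10 to -0.59) and NK cell markers (2.78 to -0.80). Without ATPlow vehicle 3 alone the cell cycle median was -0.37, and without ATPint vehicle 3 the autophagy median was 0.31. The count was 146, 1002, 24 and 15 without ATPlow vehicle 1, 2, 3 and 4, and 138, 28, 1290 and 78 without ATPint vehicle 1, 2, 3 and 4. Of 32 named calls, 14, 0, 25 and 28 were lost without ATPlow vehicle 1, 2, 3 and 4, and 13, 26, 0 and 19 without ATPint vehicle 1, 2, 3 and 4. SQSTM1, IRS2, FLCN and RRAGC were called in all 8 of these fits, HILPDA, TTC22, NR1D2 and FNIP1 in 6, LDHA, PNPT1 and PIK3IP1 in 5, and DDIT3, P2RX7, LY9, LIMA1, HK2, SLC17A5, SMPD1 and CTSF in 4. B3GALT2 and SH3D21 were called in 3, and OSBPL10, HPDL, KISS1R, SLC29A1, TPI1, UHRF1, MCM4, MCM5, PINK1, DNM1L and VDAC1 in 2 (highest adjusted p = 0.151, for VDAC1). Without ATPint vehicle 1 the log2 fold change went from -2.11 to -1.35 for HPDL, from -1.55 to -0.94 for LIMA1 and from -1.36 to -0.88 for SLC29A1.

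The comparison of CsA with vehicle in ATPlow cells holds any effect of the compound. It may also hold differences between people, as vehicle and CsA libraries of the same number matched no better than those of different numbers (below). Of 31 genes of the integrated stress response, the program that slows protein synthesis under stress, 6 were lower and 25 did not pass (median log2 fold change -1.05, camera adjusted p = 9.81e-28; adjusted p = 0.146 with an estimated correlation). PPP1R15A, which encodes a phosphatase subunit that ends this response, stood at 55.4 ± 10.2 CPM with CsA and 246 ± 43.1 with vehicle (SD, n = 4 each; log2 fold change -2.15 ± 0.29 SE, edgeR adjusted p = 0.00235). DDIT3 was 6.04-fold lower, TRIB3, a pseudokinase of the same program, 4.10-fold, ATF3, a stress-induced transcription factor, 3.20-fold, and SLC3A2, a subunit of amino acid transporters, 2.55-fold. SQSTM1 stood at 248 ± 18.9 CPM with CsA and 727 ± 53.7 with vehicle (log2 fold change -1.55 ± 0.13 SE, edgeR adjusted p = 4.71e-05). GTF2IRD1 was 5.65-fold lower, the kinase gene RPS6KA2 3.88-fold and P2RX7 3.73-fold. CXCL8, a chemokine for neutrophils, stood at 6.71 ± 4.03 CPM with CsA and 104 ± 97.6 with vehicle (edgeR adjusted p = 0.0254), where the vehicle libraries lay between 14.1 and 199 CPM.

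Genes higher with CsA included the cytoplasmic actins. ACTB stood at 11892 ± 1665 CPM with CsA and 5159 ± 874 with vehicle (SD, n = 4; edgeR adjusted p = 0.00149), and ACTG1 was 2.38-fold higher. In ATPint, ACTB stood at 10878 ± 1175 CPM with vehicle and 12196 ± 1174 with fMet. ATPlow with vehicle was thus the group set apart for this gene. MYL6, a myosin light chain, was 1.96-fold higher with CsA, PCLAF, which binds the replication clamp, 2.08-fold, and GINS2 of the replicative helicase 1.85-fold. MRPL23 of the mitochondrial ribosome was 2.10-fold higher, NINJ2 1.92-fold and CASS4 1.90-fold. In all, 35 genes were higher and 76 lower of 15980 tested, 2291 genes had an unadjusted p below 0.05 where 799 are expected, and 111 of the 111 called genes showed no overlap between the groups (10.5% of all genes, 2.86% by chance). Of these 111, 1 was of the classes not named. With only the 8 libraries of this comparison, which hold no fMet library, edgeR called 71 genes, 54 of them among the 111.

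FLCN, RRAGC and FNIP1 were named after their values were seen. Their products, folliculin, a Rag GTPase and a partner of folliculin, act together at the lysosome in nutrient sensing. FLCN (ENSG00000154803, hg38 chromosome 17, 17212212 to 17237188) stood at 28.4 ± 3.13 CPM with CsA and 73.3 ± 7.57 with vehicle (SD, n = 4; log2 fold change -1.37 ± 0.12 SE, edgeR adjusted p = 4.71e-05). RRAGC was 2.11-fold and FNIP1 2.22-fold lower with CsA, with adjusted p of 0.00133 and 0.00235. All of FLCN, RRAGC and FNIP1 were also higher in ATPlow than in ATPint under vehicle, by 2.26-fold, 1.93-fold and 1.83-fold, with adjusted p of 0.000540, 0.00398 and 0.0192. Both comparisons use the ATPlow vehicle libraries, which by itself favours opposite directions. No list of genes of this kind was fixed beforehand or tested.

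**Figure D2:**
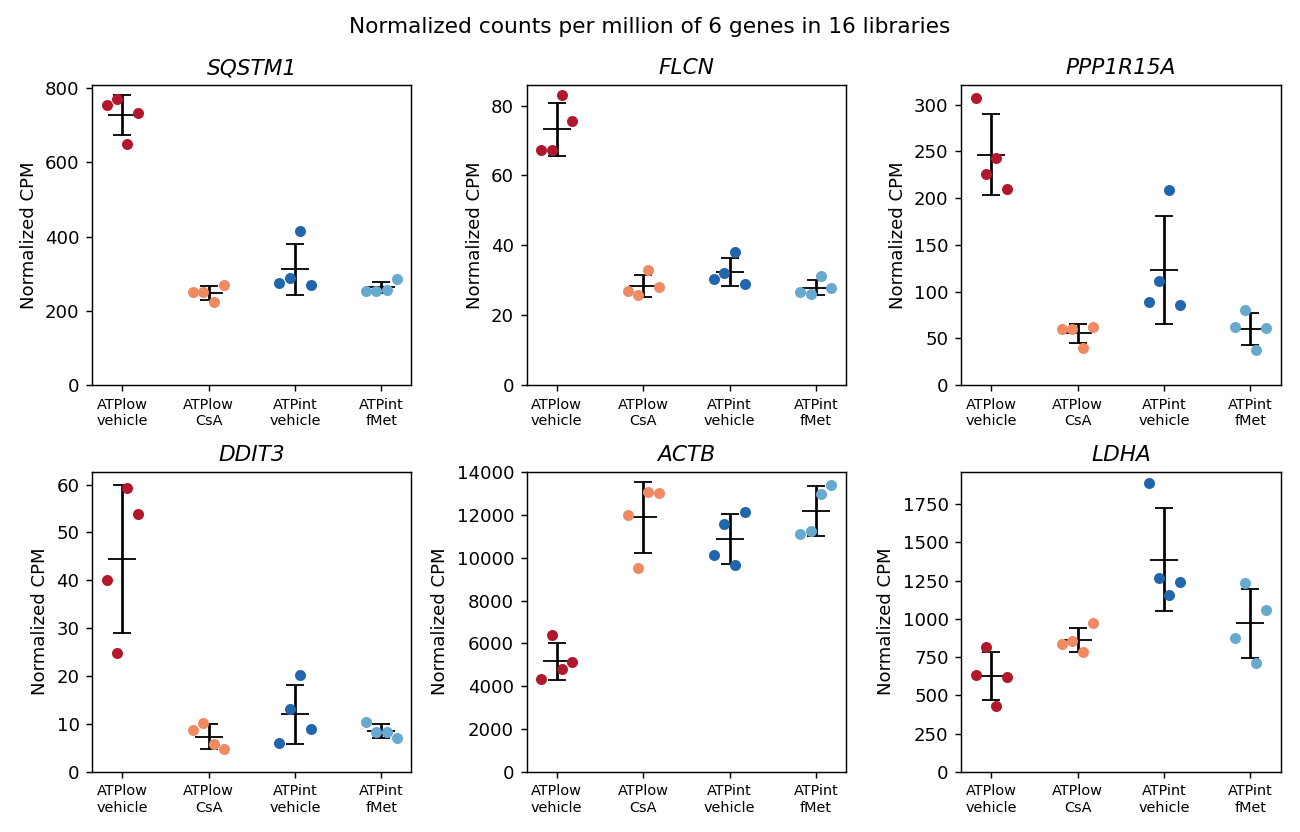
Normalized CPM of SQSTM1, FLCN, PPP1R15A, DDIT3, ACTB and LDHA in 16 libraries. Points are libraries, bars the mean and SD of 4; SQSTM1 lies at 650 to 771 CPM in ATPlow with vehicle and at 223 to 415 CPM in the 12 other libraries.

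Adjusted over the list alone, 28 of the 31 members of the integrated stress response were lower (fry adjusted p = 0.00492). The respiratory chain had a median of 0.26 with 0 of 76 members past the edgeR threshold over all genes and 10 higher adjusted over the list alone (camera adjusted p = 3.90e-14; adjusted p = 0.717 with an estimated correlation). The cell cycle list had a median of 0.36 with 1 of 45 higher, also 1 adjusted over the list alone (camera adjusted p = 3.71e-09, or 0.721 with an estimated correlation). The type I interferon response had a median of -0.48, with 3 of 35 lower adjusted over the list alone (camera adjusted p = 8.54e-07; adjusted p = 0.721 with an estimated correlation). Calcineurin-NFAT dependent activation genes had a median of -0.45, with 1 of 36 lower adjusted over the list alone (camera adjusted p = 0.0122; adjusted p = 0.865 with an estimated correlation). The mean of this list was 3.34 log2 CPM in CsA 3, 4.81 to 5.06 in the other CsA libraries and 4.42 to 5.52 with vehicle, and camera did not call it without CsA 3 (median -0.29, adjusted p = 0.488) or ATPlow vehicle 1 (-0.23) or 2. Autophagy had 2 of 39 lower and, adjusted over the list alone, 1 higher and 7 lower (median -0.18, camera adjusted p = 0.0122; adjusted p = 0.575 with an estimated correlation). Camera also called NF-kB targets (median -0.32, adjusted p = 0.0242), the follicular helper program (-0.29, 0.0490), heat shock proteins (0.21, 0.0351), tissue homing (0.23, 0.0490) and platelet markers (1.59, 0.0383). With an estimated correlation their adjusted p were 0.721, 0.575, 0.749, 0.761 and 0.721, and in the 8 fits without 1 library camera called them in 6, 2, 5, 5 and 3. The median without CsA 3 was -0.18 for NF-kB targets, 0.12 for heat shock proteins, 0.13 for tissue homing and 1.05 for platelet markers. The lysosomal list had a median of -0.11 with 1 of 51 lower (camera adjusted p = 0.0787).

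Without the 4 monocyte-rich libraries 76 genes were called, 24 of them among the 111, and camera still called the respiratory chain (median from 0.26 to 0.10, adjusted p = 0.00614) but not the cell cycle list (from 0.36 to -0.03, 0.637), NF-kB targets (-0.03, 0.487), heat shock proteins (0.08, 0.782), tissue homing (0.13, 0.0784) or platelet markers (1.51, 0.110). The median went from -0.45 to -0.73 for the NFAT list, from -0.48 to -1.06 for the interferon list and from -0.29 to -0.55 for the follicular helper program, and with them from 0.43 to 1.70 for B cell markers, from 0.11 to 3.18 for NK cell markers and from -0.01 to 0.94 for CD8 and cytotoxic markers. Without ATPlow vehicle 3 alone the medians of the respiratory chain and cell cycle lists were 0.13 and 0.11, that of the interferon list was -0.27 without CsA 1 and -0.87 without CsA 3, and that of autophagy -0.11 without ATPlow vehicle 4. The count was 53, 233, 70 and 45 without ATPlow vehicle 1, 2, 3 and 4, and 44, 48, 43 and 42 without CsA 1, 2, 3 and 4; SQSTM1, FLCN, RRAGC, FNIP1, PPP1R15A, DDIT3, TRIB3, SLC3A2, GTF2IRD1, RPS6KA2, ACTB, ACTG1 and PCLAF were called in all 8 of these fits. ATF3 was called in 6, P2RX7 in 5, MYL6 and CXCL8 in 3, MRPL23 and NINJ2 in 2, and GINS2 and CASS4 in 1 (highest adjusted p = 0.136, for CASS4); of 21 named calls, 5, 1, 5 and 6 were lost without ATPlow vehicle 1, 2, 3 and 4, and 5, 7, 7 and 5 without CsA 1, 2, 3 and 4.

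The comparison of fMet with vehicle in ATPint cells holds any effect of this amino acid. Differences between people may enter here too, as vehicle and fMet libraries of the same number matched no better than those of different numbers (below). SNX29, a member of the sorting nexin family, stood at 89.6 ± 16.3 CPM with fMet and 39.0 ± 9.34 with vehicle (SD, n = 4; 2.30-fold higher, SE of the log2 fold change 0.18, edgeR adjusted p = 0.0300). LINC00511, a long noncoding RNA named after its values were seen, stood at 3.07 ± 0.93 and 0.925 ± 0.09 CPM (log2 fold change 1.73 ± 0.25 SE, adjusted p = 0.0300). A further gene, lower with fMet, was of the classes not named. This gene and 1 of the 2 higher genes were also called in the same direction with CsA, so they were not particular to fMet. LINC00511 stood at 3.48 ± 0.59 CPM with CsA and 1.48 ± 0.14 in ATPlow with vehicle. In all, 2 genes were higher and 1 lower of 15980 tested, while 2641 genes had an unadjusted p below 0.05 where 799 are expected, and DESeq2 called 386. With only the 8 libraries of this comparison edgeR called 0 genes (2012 unadjusted), with an adjusted p of 0.219 for both SNX29 and LINC00511. Of all genes, 8.65% showed no overlap between the groups, against 2.86% by chance.

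Genes with the smallest p that did not pass included the integrin ITGB1 (331.5 ± 68.6 against 185 ± 21.8 CPM), the ceramide kinase CERK (214 ± 16.8 against 130 ± 19.6 CPM) and the vesicle fusion protein gene VAMP3 (32.4 ± 4.32 against 21.1 ± 1.71 CPM; SD, n = 4 each). Fold values above vehicle were 2.70 for ANTXR2, 1.60 for SLCO3A1, 1.46 for MAN1A2, 1.41 for EIF4EBP2 and 17.4 for B3GALT2. IRF7, a transcription factor of interferon responses, stood at 103 ± 34.8 CPM with fMet and 299.5 ± 44.7 with vehicle. Fold values below vehicle were 1.56 for IDH3A of the citric acid cycle, 3.00 for VSIG10L, 2.51 for PNPT1, 1.48 for NAPA, 1.60 for TIPIN, 1.45 for CMTR1 and 4.11 for the nucleoside transporter SLC28A3. Adjusted p of these 16 genes lay between 0.0884 and 0.139 by edgeR.

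The 7 lists below were called by camera under fMet, each with 0 members past the edgeR threshold over all 15980 genes (2641 genes at an unadjusted p below 0.05, 386 called by DESeq2) and each with an adjusted p of 0.512 with an estimated correlation. The type I interferon response had a median log2 fold change of -1.03 (camera adjusted p = 4.16e-18), with 20 of 35 members lower adjusted over the list alone. Its mean was 5.06, 5.41, 6.79 and 5.68 log2 CPM in fMet 1 to 4. With vehicle it was 6.62 to 6.92, so fMet 3 lay at the vehicle level. In CsA 1 to 4 it was 5.07, 5.45, 6.69 and 5.62, so the pattern went with the number and was not particular to fMet. Calcineurin-NFAT dependent activation genes (median -1.03, adjusted p = 6.24e-06) had 1 of 36 lower adjusted over the list alone, glycolysis (-0.41, 5.68e-07) 1 of 24, and the integrated stress response (-0.54, 6.58e-07) 0 of 31. Tissue homing, adhesion and invasion had a median of 0.57 (adjusted p = 1.09e-05), with 18 of 43 members higher and 3 lower adjusted over the list alone. The lysosomal list (median 0.53, adjusted p = 3.71e-08) had 0 of 51 members past the threshold adjusted over the list alone, and naive and central memory T cell genes (0.32, 0.00264) had 3 of 15 higher. The NFAT list mean was 6.96 log2 CPM in ATPint vehicle 1 and 4.96 to 5.59 in the other vehicle libraries, and 3.24 in fMet 3 and 4.85 to 5.27 in the other fMet libraries. Without ATPint vehicle 1 its median was -0.27 (camera adjusted p = 0.0137) and that of naive and central memory genes 0.16.

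Markers of other cells stood higher with fMet. Median log2 fold changes were 3.50 for monocyte and macrophage markers (camera adjusted p = 0.0433), 2.73 for NK cell markers (0.0205), 2.00 for B cell markers (0.000253) and 1.72 for platelet markers (0.00292). With an estimated correlation these adjusted p were 0.599, 0.599, 0.512 and 0.512, and adjusted over the list alone 5 of 11, 0 of 10, 2 of 10 and 3 of 5 members were higher. CsA libraries of the same number held similar levels, so these were not particular to fMet. B cell marker means were 3.79, 3.42, 3.66 and 0.92 log2 CPM in fMet 1 to 4 and 3.74, 3.31, 3.68 and 0.70 in CsA 1 to 4. Red cell markers, too few for a list test, had a median log2 fold change of 2.59 with fMet and 2.22 with CsA. The lysosomal mean was 6.55 log2 CPM in the monocyte-rich fMet 3 and 5.58 to 5.69 in the other fMet libraries, and the homing mean 6.84 against 5.88 to 6.04. Without the 4 monocyte-rich libraries, of which this comparison holds fMet 3, the median of the lysosomal list went from 0.53 to 0.17 (camera adjusted p = 5.67e-05) and of the homing list from 0.57 to 0.30 (1.64e-05). Camera also still called the interferon (-1.41, 4.64e-43), glycolysis (-0.32, 5.42e-05), stress response (-0.50, 4.47e-06), NFAT (-0.80, 0.000128) and naive and central memory lists (0.25, 0.00268), B cell (2.01, 0.000423), NK cell (2.35, 0.0399) and platelet markers (1.54, 0.0152), but not monocyte and macrophage markers (1.26, 0.144).

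Without the 4 monocyte-rich libraries 54 genes were called, 3 of them the same as with all libraries. The count was 1 without ATPint vehicle 1, 2 or 3 or fMet 2 or 3, and 2 without ATPint vehicle 4 or fMet 1 or 4; SNX29 was called only without ATPint vehicle 4 or fMet 4 (highest adjusted p = 0.162) and LINC00511 only without fMet 1 (0.221).

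**Figure D3:**
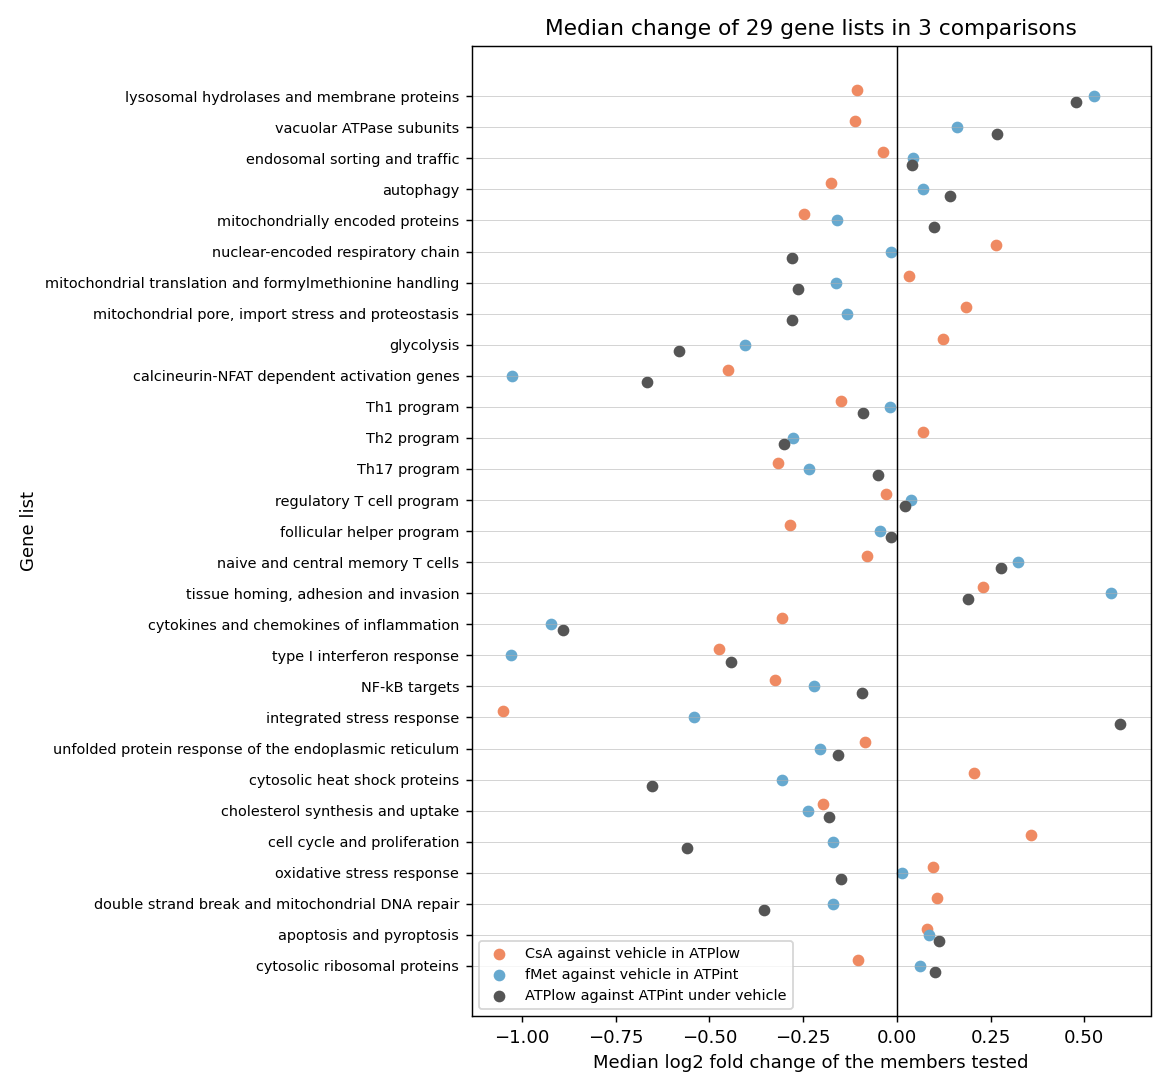
Median log2 fold change of the tested members of each gene list, with 1 point per comparison. The integrated stress response lies at -1.05 for CsA, -0.54 for fMet and 0.59 for ATPlow against ATPint; lists are defined in the section on processing.

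The difference of the responses to CsA and fMet was tested directly, although treatment and patient group changed together. FLCN (log2 difference -1.15 ± 0.16 SE) and SQSTM1 (-1.31 ± 0.19 SE) passed, each with an edgeR adjusted p of 0.0296, in the fit that takes CsA and fMet libraries of the same number as independent. With 1 term per number shared by these libraries, which deviated together (below), edgeR called 0 genes (2160 unadjusted), and the adjusted p were 0.0892 and 0.103 for the same log2 differences; this fit was chosen after the values were seen, and DESeq2 was not run in it. Under fMet, FLCN stood at 27.9 ± 2.25 CPM against 32.4 ± 4.01 with vehicle, and SQSTM1 at 263 ± 16.04 against 311 ± 69.2 (SD, n = 4). With CsA they stood at 28.4 ± 3.13 and 248 ± 18.9 CPM, close to the fMet levels. In ATPlow with vehicle they stood at 73.3 ± 7.57 and 727 ± 53.7 CPM. For these genes the difference of responses thus mostly restates that between the vehicle groups. Unadjusted, 1713 genes had a p below 0.05, and DESeq2 called 131 genes. Camera called 14 of 35 lists, among them the cell cycle (median difference 0.52, adjusted p = 9.61e-13), glycolysis (0.47, 4.87e-07), the respiratory chain (0.30, 2.26e-09), the lysosomal list (-0.57, 2.26e-09), autophagy (-0.18, 0.000252) and the integrated stress response (-0.72, 2.35e-08). Their adjusted p with an estimated correlation were 0.423, 0.423, 0.448, 0.432, 0.423 and 0.423. Without the 4 monocyte-rich libraries these medians were 0.16, 0.26, 0.16, -0.37, -0.24 and -0.50, each still called by camera. Without fMet 3 alone the lysosomal median was -0.26, and without ATPlow vehicle 3 that of the respiratory chain 0.20. Markers of other cells differed too. Median differences were -1.38 for monocyte and macrophage, -2.76 for NK cell and -1.63 for B cell markers. They were -0.61 for CD8 and cytotoxic and -0.22 for platelet markers. Without the monocyte-rich libraries these were 0.32, 0.69, -0.39, 0.37 and -0.19 in the same order, so monocyte, NK cell and CD8 markers changed sign.

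The count of 2 became 4 without ATPlow vehicle 3, 1 without CsA 3 and 5 without ATPint vehicle 3, and 0 by edgeR without any 1 of the other 13 libraries, with 1167 to 2199 genes at an unadjusted p below 0.05. FLCN stayed past the threshold in 3 of the 16 fits (without ATPlow vehicle 3, CsA 3 or ATPint vehicle 3; highest adjusted p = 0.136) and SQSTM1 in 2 (without ATPlow vehicle 3 or ATPint vehicle 3; 0.136).

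Fold changes were compared across genes, which are not independent replicates. Across 15980 genes the fMet response went with the difference of ATPlow from ATPint (Pearson r = 0.782, Spearman rho = 0.632, covariance 0.530). Both contrasts use the ATPint vehicle libraries, and simulated data without differences gave a mean r of 0.505 and a covariance of 0.127. With the vehicle libraries divided between the contrasts the mean over 6 splits was r = 0.517 and covariance 0.449, and without the 4 monocyte-rich libraries r was 0.350. The last value still shares the vehicle libraries and has no simulated value of its own, so it shows no relation beyond the sharing. The CsA response against the same difference gave r = -0.206 (rho = -0.386, covariance -0.0869), where simulated data gave r = -0.507 and covariance -0.126; with the vehicle libraries divided the mean r was 0.0458, between -0.187 and 0.528, and the covariance 0.0705. Among called genes, 16 were higher with CsA and lower in ATPlow (0.477 expected if independent) and 44 were lower with CsA and higher in ATPlow (0.866 expected), SQSTM1, FLCN, DDIT3 and P2RX7 among the latter. Both sets of calls share the ATPlow vehicle libraries, which by itself gives overlap in these directions. With these libraries divided between the contrasts, 2 to 18 genes over 6 splits were lower with CsA and higher in ATPlow (at most 2.94 expected) and 0 to 2 higher with CsA and lower in ATPlow (at most 0.444 expected). In the same direction, 0 to 8 were lower in both (at most 4.09 expected), with overlap in 1 split, and 0 were higher in both. The 8 and the 18 came from the same split. The CsA and fMet responses, which share no library, gave r = 0.382 (rho = 0.248, covariance 0.181, simulated mean r -0.0158). Treated libraries of the same number deviating together gave an estimated covariance of 0.0847. That estimate used log2 CPM with a prior count of 2, another scale than the fold changes, so it is not an exact share of the 0.181.

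The labels number the libraries of each group 1 to 4, without stating that a number marks the same patient with vehicle and with drug. Deviations of log2 CPM from the group mean were correlated across genes between libraries of different groups. For CsA and fMet libraries of the same number, which the labels assign to different patient groups, r was 0.682 to 0.901, against at most 0.0115 for different numbers. Subtracting the group mean by itself lowers r for different numbers where same numbers go together, so the latter value is no independent baseline. Without this subtraction the root mean square difference of log2 CPM was 0.372 to 0.447 for the same number and 0.690 to 1.18 for different numbers. In 8 of 8 CsA and fMet libraries the closest partner in the other treated group had the same number. For vehicle and CsA libraries of the same number r was -0.357 to 0.530, and 2 of 8 had their own number as closest partner. For vehicle and fMet libraries of the same number r was -0.174 to -0.0331, and 0 of 8 did.

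**Figure D4:**
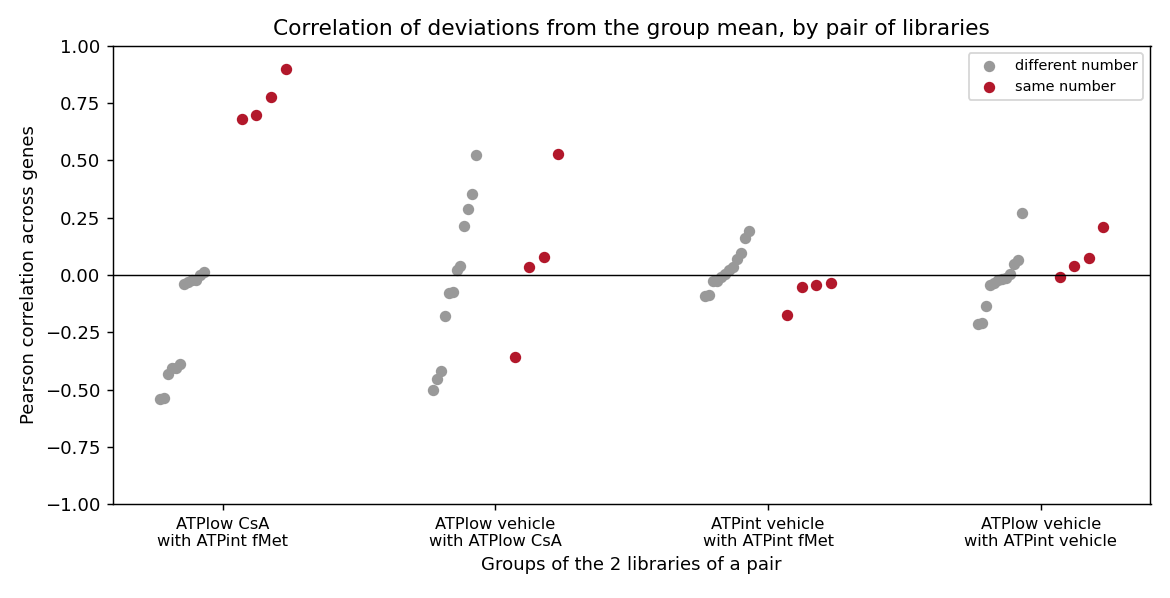
Correlation across genes of deviations from the group mean for pairs of libraries in different groups. Each point is a pair; the 4 pairs of CsA and fMet libraries with the same number lie at 0.682 to 0.901, the 12 with different numbers at or below 0.0115.

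CsA and fMet libraries were therefore also compared with the number as a block, a comparison chosen after these values were seen. The gelatinase gene MMP9 stood at 110 CPM with CsA and 157 with fMet (log2 fold change -0.51 ± 0.07 SE, edgeR adjusted p = 0.0226, lower in 4 of 4 pairs), and IDO1, a tryptophan-degrading enzyme, CHI3L1 and the glutamine synthetase GLUL were also lower with CsA (-0.42, -0.59 and -0.34). Monocyte and macrophage markers were lower with CsA in 9 of 9 members (median -0.23, camera adjusted p = 7.03e-07; adjusted p = 0.467 with an estimated correlation), and their sums in the pair numbered 3 were 1598 CPM with CsA and 2176 with fMet. In the pairs numbered 1, 2 and 4 the sums were nearly equal, at 60.9 and 62.1, 47.4 and 46.3, and 30.8 and 31.7 CPM with CsA and with fMet. FAM193B (0.48), U2AF1L5 (1.21), the splicing factor SRSF5 (0.26), NBPF20 (1.23), PGGHG (0.40) and GOLGA8B (0.55) were higher with CsA. These 10 genes were all those past the threshold of 14955 tested, with 1336 at an unadjusted p below 0.05. The common coefficient of biological variation was 6.07% with the block and 34.7% without it, where edgeR called 0 genes and 78 had an unadjusted p below 0.05; DESeq2 was not run here. Camera called 19 of 35 lists, 18 of them lower with CsA, with the smallest p for the integrated stress response (30 of 31 members lower, median -0.14, adjusted p = 2.36e-11), glycolysis (22 of 24, -0.13, 1.69e-10) and the lysosomal list (42 of 51, -0.08, 1.12e-08); with an estimated correlation the adjusted p of each was 0.487. Calcineurin-NFAT dependent activation genes were lower with CsA than with fMet in 24 of 35 members (median -0.09, camera adjusted p = 4.77e-05; adjusted p = 0.507 with an estimated correlation), and the early response genes EGR1 and EGR2 and the receptor gene TNFRSF9 had log2 fold changes of -0.40, -0.34 and -0.24, each lower in 4 of 4 pairs with an adjusted p of 0.0923. EGR1, EGR2 and TNFRSF9 had the smallest p of this list. Its members IL2, TNF, IL13 and XCL2 had log2 fold changes of 0.07, 0.06, 0.10 and 0.30. Cytosolic ribosomal proteins were lower with CsA in 61 of 70 members, so a shift of this kind was not particular to NFAT genes. The count of 10 called genes became 6, 8, 38 and 17 without the pair numbered 1, 2, 3 and 4.

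The genes named whatever their result gave these values. IL2, the T cell growth factor, stood at 4.23 ± 5.05 CPM in ATPlow with vehicle, 0.792 ± 0.52 with CsA, 24.6 ± 41.0 in ATPint with vehicle and 0.738 ± 0.45 with fMet (SD, n = 4), and ATPint vehicle 1 alone reached 86.1 CPM. This library also stood at 534 CPM of CSF2 (13.3 to 26.6 in the other 3), 296 of TNF (55.4 to 95.6) and 51.3 of IL21 (14.6 to 23.8). For CsA the log2 fold changes were -2.43 for IL2, -1.01 for IFNG, -0.15 for TNF, -0.37 for IL17A, -1.11 for IL21 and -0.93 for CSF2. For fMet they were -5.07 for IL2, -1.91 for IFNG, -0.98 for TNF, -0.68 for IL17A, -1.85 for IL21 and -3.05 for CSF2. The fMet means of CSF2 and TNF, 17.8 and 64.6 CPM scaled over the CsA and fMet libraries, lay within the range of the other 3 ATPint vehicle libraries. ATPint vehicle 1 thus carried most of the CSF2 and TNF changes, while the fMet mean of IL21, 7.52 CPM, lay below that range. None of these 6 cytokine genes passed in any of the 3 comparisons (lowest edgeR adjusted p = 0.168, for IL2 with fMet). LAMP1, a membrane protein of lysosomes, had log2 fold changes of -0.20 with CsA, 0.39 with fMet and 0.52 for ATPlow against ATPint (lowest adjusted p = 0.0533), and TFEB, a transcription factor of lysosomal genes, -0.25, 0.38 and 0.66 (lowest 0.150). PPIF, cyclophilin D, had values of -0.14, -0.53 and -0.44, MTFMT, which formylates the initiator methionine, 0.14, -0.03 and -0.17, MRE11, a DNA repair nuclease, 0.34, 0.04 and -0.28, and SH3PXD2A, a scaffold of invasive protrusions, -0.32, 0.05 and 0.40; none passed (lowest adjusted p = 0.260). The receptors for formyl peptides FPR1 and FPR2 were below the filter, with 95 and 480 counts over all libraries. FPR3 was at 0 in the 4 ATPint vehicle libraries and reached 55.7 CPM in CsA 3 and 78.2 CPM in fMet 3, both monocyte-rich.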

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

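Tests chosen only after the results were seen were the splits of the samples, the correction for GC content and gene length, the comparison of CsA and fMet libraries of the same number, the block of these libraries in the difference of responses, and the tests on deviations, counts and on or off genes of same-number libraries. The fits without monocyte-rich libraries were added after the marker sums were seen. In 459 groups of 4 values (measures per library and named genes), 49 had a library far from the other 3 by Dixon's test, where chance gives about 1 in 20 or 22.95. Of these, 10 were in fMet 3, 9 in ATPint vehicle 1 and 8 in CsA 3.

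CsA and fMet libraries of the same number, which the labels give to different patient groups, deviated alike from their group means (r across genes 0.682 to 0.901). A single library deposited under both labels would give a chi-square of the counts per degree of freedom near 1, and the lowest of the 4 pairs was 2.96. Cells of the monocyte type in both as the whole cause are argued against by the 6145 genes that hardly followed their marker sum, where the lowest same-number r was 0.539 and the highest different-number r 0.0432, while other cell types stay open, as these r were 0.1995 and 0.0642 over the 994 genes that hardly followed any of 8 marker sums. Over 19 genes on in some libraries and off in others, a set whose definition was tightened after a first result, same-number CsA and fMet libraries matched in 100% in each pair and different numbers in at most 73.7%, in line with cells of the same people in both. Which step or label would account for this stays open, and no biological explanation was tested.

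Between ATPlow and ATPint under vehicle 400 genes were called. Cells of the monocyte type in 2 ATPlow vehicle libraries as the whole cause are argued against by the median ratio of the log2 fold change without to that with the 4 monocyte-rich libraries, 0.842 (lower quartile 0.726), with 400 of 400 genes in the same direction; 12 stayed called, as the median size went from 0.749 to 0.626 and the median SE from 0.162 to 0.178 with fewer libraries. After a correction for GC content and gene length the median ratio was 0.993. Of 35 splits of the 8 libraries, 1, the real one, gave as many genes and the highest other gave 4, the smallest share that 35 splits can give. This argues against a chance split in the fit of 16 libraries only, as with only the 8 libraries the real split gave 0 by edgeR (2754 unadjusted). The patient group, any other difference between the people sampled and the time in culture, which is not stated for ATPlow, stay open.

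Between CsA and vehicle in ATPlow 111 genes were called. Cells of the monocyte type as the whole cause are argued against by a median ratio of 0.929 without the monocyte-rich libraries (lower quartile 0.830; median size 0.875 and 0.786, median SE 0.149 and 0.181, 24 still called with fewer libraries). Over the 111 genes the median ratio of fMet to CsA log2 fold changes was 0.198 (upper quartile 0.390), and 84 had the same direction with fMet. The genes were chosen for their CsA change, which by itself lowers this ratio, by an amount that was not tested. The ratio alone thus does not settle whether a difference between vehicle and treated libraries shared by both patient groups was the whole cause. A part played by it stays open too. A chance split is argued against, as 1 of 35 splits, the real one, gave as many genes and the highest other gave 0 by edgeR (2291 genes at an unadjusted p below 0.05 in the real one, 690 called by DESeq2). This is the smallest share that 35 splits can give. Vehicle and CsA libraries of the same number matched in 63.2% to 68.4% of the on or off genes and those of different numbers in 47.4% to 73.7%, consistent with different people behind them, so that an effect of CsA and a difference between people both stay open. A distance was also taken over 4 genes that follow common deletions or known expression variants of single people. It was 3.02 to 4.68 for every pair of a vehicle and a treated library, in both patient groups. Between the vehicle groups it was at most 1.14 and within a group at most 2.24. For CsA and fMet libraries it was 0.0906 to 0.429 with the same number and 0.209 to 2.23 with different numbers. Different people behind vehicle and treated libraries would give such distances in both patient groups, but this was not tested further.

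Other splits were counted for the remaining gene counts. For the 3 genes of fMet against vehicle, 1 of 35 splits of the fit of 16 libraries, the real one, gave as many and the highest other gave 0 by edgeR (2641 genes at an unadjusted p below 0.05 in the real one, 386 called by DESeq2). The real split gave 0 by edgeR with only the 8 libraries (2012 unadjusted) and 1 to 2 without 1 library, so these splits do not settle chance for so small a count. A difference between people stays open, as vehicle and fMet libraries of the same number matched in 42.1% to 73.7% of the on or off genes. For the 2 genes of the difference of responses, 2 of 100 drawn splits, the real one included, gave as many and the highest other gave 11, several times the real count. The reason was not tested, and these splits take CsA and fMet libraries of the same number as independent. For the 10 genes between CsA and fMet libraries of the same number, 1 of 8 assignments gave as many and the highest other gave 6; these are too few for a share under 0.05.

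By a test of the difference of the CsA and fMet responses, FLCN (-1.15, log2) and SQSTM1 (-1.31, log2) passed the threshold, in 3 and 2 of the 16 fits without 1 library, and did not with a block of the CsA and fMet libraries only (adjusted p = 0.0892 and 0.103). Their levels with CsA and with fMet were close, so the difference lay mostly between the vehicle groups.

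Libraries far from the other 3 of their group in mean log2 CPM of a list were the following. CsA 3 had 6.35 for the lysosomal list (others 5.57 to 5.66), 6.25 for vacuolar ATPase subunits (5.80 to 5.84), 6.70 for tissue homing (5.84 to 5.98) and 3.34 for calcineurin-NFAT dependent genes (4.81 to 5.06). fMet 3 had 6.55 for the lysosomal list (5.58 to 5.69), 6.38 for vacuolar ATPase subunits (5.81 to 5.89), 6.84 for tissue homing (5.88 to 6.04), 2.67 for cytokines and chemokines (4.27 to 4.50) and 2.17 for neutrophil markers (-1.31 to -0.80). ATPint vehicle 1 had 5.78 for endosomal sorting (5.75 to 5.76), 6.93 for naive and central memory genes (7.54 to 7.66), 6.05 for cytokines and chemokines (4.19 to 4.46), 6.25 for cholesterol synthesis (6.55 to 6.60) and 1.03 for red cell markers (-0.89 to -0.69). CsA 2 had 5.46 for autophagy (5.39 to 5.39), 5.66 for apoptosis (5.55 to 5.56) and 7.05 for CD8 and cytotoxic markers (4.83 to 5.10). fMet 2 had 6.80 for heat shock proteins (6.42 to 6.47) and 7.06 for CD8 and cytotoxic markers (4.88 to 5.25). B cell markers had 0.70 in CsA 4 (3.31 to 3.74), 2.72 in ATPint vehicle 4 (-0.26 to -0.14) and 0.92 in fMet 4 (3.42 to 3.79). ATPlow vehicle 3 had 5.47 for autophagy (5.58 to 5.59) and ATPlow vehicle 2 had 5.997 for the regulatory program (5.42 to 5.48). The total count of fMet 4 was 18225432 (23531978 to 23750093).

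Libraries far from the other 3 in the normalized CPM of a named gene were the following. ATPint vehicle 1 had 5.15 CPM of TTC22 (others 15.5 to 17.3), 30.4 of TIPIN (21.4 to 21.9), 107.7 of SLC29A1 (37.7 to 44.2) and 4.18 of LY9 (16.7 to 20.7). fMet 3 had 76.0 CPM of LIMA1 (53.8 to 56.7), 21.7 of CASS4 (16.3 to 16.7), 65.05 of SMPD1 (36.0 to 38.7), 295.7 of LAMP1 (219.8 to 223.9) and 78.2 of FPR3 (0 to 0.132). CsA 3 had 40.1 CPM of PPP1R15A (59.6 to 61.7), 242.7 of EIF4EBP2 (200.7 to 205.6), 61.0 of SMPD1 (37.6 to 39.7) and 55.7 of FPR3 (0 in the others). ATPlow vehicle 4 had 60.8 CPM of SNX29 (45.5 to 46.5) and 15.2 of TIPIN (14.4 to 14.5), and ATPlow vehicle 1 had 24.8 of VAMP3 (28.4 to 29.01). SQSTM1 had 414.6 CPM in ATPint vehicle 3 (268.3 to 287.3) and 286.8 in fMet 4 (253.2 to 257.2). ATPint vehicle 4 had 17.2 CPM of IL17A (12.1 to 12.7), ATPint vehicle 3 had 20.9 of SLC17A5 (14.2 to 14.3) and ATPint vehicle 2 had 164.2 of CMTR1 (147.0 to 149.4). CsA 4 had 8.84 CPM of PINK1 (15.04 to 16.05), CsA 2 had 3.16 of HPDL (4.13 to 4.16) and fMet 1 had 3.03 of VSIG10L (2.08 to 2.21).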

How the results depend on the processing

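The fits without monocyte-rich libraries, with the marker sum as a covariate, with the GC and length correction, of CsA against fMet by number and with a block of the CsA and fMet libraries only were chosen after seeing the data. None of the named genes past a threshold reversed direction under any setting, and of these 57 calls, all stayed past it with DESeq2 size factors, the stricter filter and DESeq2, 17 without the monocyte-rich libraries and 3 with the number as a block. Simulated genes changed 2-fold were recovered by edgeR in 60%, 45.7% and 50% of cases for CsA, fMet and ATPlow against ATPint, so smaller counts here do not show that genes did not differ. Unless a cause is given, it was not tested.

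The count for CsA (111) became 189 with the stricter filter, which tests fewer genes, 690 with DESeq2, 44 with an absolute log2 fold change of at least 1, 71 with only the 8 libraries, 4 with the number as a block, 547 with the marker covariate, and 42 to 233 without 1 library. The count for fMet (3; 2641 unadjusted) became 386 with DESeq2, 54 without the monocyte-rich libraries, 15 with the covariate, 1 with the GC and length correction, 1 to 2 without 1 library, and 0 by edgeR with only the 8 libraries (2012 unadjusted) or with the block (1630). The count for ATPlow against ATPint (400) became 149 with no filter, which tests more genes, 687 with the stricter filter, 1857 with DESeq2, 100 with an absolute log2 fold change of at least 1, 15 without the monocyte-rich libraries, 15 to 1290 without 1 library, and 0 by edgeR with only the 8 libraries (2754 unadjusted) or with the block (2751). The count for the difference of responses (2) became 1 with upper quartile normalization, 131 with DESeq2, 0 to 5 without 1 library, and 0 by edgeR with no filter (2350 unadjusted), with the block (1474), with a block of the CsA and fMet libraries only (2160) or without the monocyte-rich libraries (913).

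The lists called by camera (11 for CsA, 21 for fMet, 13 for ATPlow against ATPint, 14 for the difference of responses) became 0, 0, 0 and 0 with an estimated correlation and 1, 0, 7 and 0 with fry. The correlation of the fMet response with the ATPlow difference (0.782) became 0.517 with divided vehicle libraries and 0.350 without the monocyte-rich libraries. That of the CsA response (-0.206) became 0.0458, a reversed sign, with divided vehicle libraries, which removes the shared libraries, -0.812 over genes called between ATPlow and ATPint, which were chosen on the shared libraries, -0.330 at a mean log2 CPM of at least 3 and -0.467 without the monocyte-rich libraries. That of the CsA with the fMet response (0.382) became 0.560 without the monocyte-rich libraries. The 10 genes between CsA and fMet libraries became 0 by edgeR without the block (78 unadjusted) and 6 to 38 without 1 pair.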

Other observations

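Lists not called by camera in any of the 3 comparisons had these median log2 fold changes for CsA, fMet and ATPlow against ATPint. The helper programs had -0.15, -0.02 and -0.09 (Th1), 0.07, -0.28 and -0.30 (Th2) and -0.32, -0.23 and -0.05 (Th17), and the regulatory program -0.03, 0.04 and 0.02. Endosomal sorting and traffic had -0.04, 0.04 and 0.04, mitochondrially encoded proteins -0.25, -0.16 and 0.10, and cytosolic ribosomal proteins -0.10, 0.06 and 0.10. The oxidative stress response had 0.10, 0.01 and -0.15, and apoptosis and pyroptosis 0.08, 0.09 and 0.11. CD4 T cell markers had 0.17, 0.26 and -0.05, and CD8 and cytotoxic markers -0.01, 0.83 and 0.49. Markers of red cells (2.22, 2.59 and 0.52), dendritic cells (-0.11, -0.14 and -0.36) and neutrophils (0.29, 0.88 and 0.82) had too few members for a list test. Median, mean and direction of the camera test differed in sign under CsA for the Th1 and Th2 programs, oxidative stress, apoptosis and mitochondrial translation, under fMet for the Th1 program, oxidative stress and the respiratory chain, and in ATPlow against ATPint for the Th1, Th17 and follicular helper programs, NF-kB targets and oxidative stress. Median and mean of dendritic cell markers differed in sign under CsA and fMet.

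Further lists were called by camera in 1 or more comparisons. Under fMet these were the unfolded protein response (median -0.21, adjusted p = 0.00645), cytokines and chemokines of inflammation (-0.92, 0.0103), NF-kB targets (-0.22, 0.0135), cholesterol synthesis (-0.24, 0.0135), mitochondrial pore and proteostasis (-0.13, 0.0205), DNA repair (-0.17, 0.0273), mitochondrial translation (-0.16, 0.0424), heat shock proteins (-0.31, 0.0430), the cell cycle (-0.17, 0.00464) and vacuolar ATPase subunits (0.16, 0.0135), each with 0 members past the edgeR threshold over all genes (2641 genes unadjusted, 386 called by DESeq2). With an estimated correlation these adjusted p were 0.512 for all but cholesterol synthesis and the cell cycle (0.622). In the 8 fits without 1 library camera called them in 7, 6, 6, 5, 7, 5, 4, 3, 7 and 6. Without ATPint vehicle 1 camera called neither cytokines and chemokines (-0.29, 0.310) nor the unfolded protein response (-0.13), the pore (-0.05), DNA repair (-0.09), mitochondrial translation (-0.06), heat shock proteins (-0.14) or NF-kB targets (-0.18). Without fMet 3 it called neither cholesterol synthesis (-0.02, 0.432) nor vacuolar ATPase subunits (0.07, 0.347), NF-kB targets (-0.14) or the cell cycle (-0.10), nor cytokines and chemokines, DNA repair, mitochondrial translation or heat shock proteins. The median was -0.15 for cholesterol synthesis without ATPint vehicle 2, -0.28 for mitochondrial translation without ATPint vehicle 3, and 0.27 for vacuolar ATPase subunits and -0.35 for NF-kB targets without fMet 2. Without the 4 monocyte-rich libraries camera no longer called cytokines and chemokines (-0.79, 0.0615), NF-kB targets (-0.15, 0.140), cholesterol synthesis (-0.04, 0.174), DNA repair (-0.14, 0.0662), mitochondrial translation (-0.18, 0.0662), heat shock proteins (-0.25, 0.140) or vacuolar ATPase subunits (0.05, 0.253), and the cell cycle median was -0.11.

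In ATPlow against ATPint camera called DNA repair (-0.36, 0.000288; adjusted p = 0.324 with an estimated correlation; -0.23 without the monocyte-rich libraries), the interferon response (-0.44, 0.000288; 0.806) and naive and central memory genes (0.28, 0.00579; 0.415).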
